A study of Homo sapiens with 6 samples.

How the data were processed

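The labels described 6 RNA samples of U2OS cells: 1 input from shNC cells, 1 input from shDNMT1 cells, and 2 samples of RNA co-immunoprecipitated with an NSun2 mutant from each. The deposited values used here were 2 tables of FPKM per gene, each with a gene identifier, a gene name, a locus and an FPKM column, per the file headers. No column of either table named a sample, a group, or input against immunoprecipitate, so both were used as tables tied to no sample, and no group was assigned from their values. The order of the 2 tables carries no meaning. Whether a table holds 1 library or several pooled is not given in the sources used here.

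FPKM is normalised by the authors for transcript length and for the number of fragments, and the tool that made it is not given in the sources used here. The submitters' processing notes name cutadapt 1.12, BWA 0.7.13, MACS 1.4.2 and the genome build hg38, without saying which of them served the FPKM tables. FPKM is a share of a total, so a difference in a few abundant RNAs moves the values of the others. The locus of a gene was often a merged interval: 47.5% of identifiers had a locus string that another identifier shared, and fragments at such loci could be divided between genes upstream. Locus starts were counted from 0 in the tables. After adding 1 they equalled the RefSeq start for 2007 genes alone at their locus, against 166 without the addition, and the coordinates printed here are counted from 1. The chosen offset could not be checked on mitochondrial genes. RefSeq annotation was matched by gene symbol for 88.2% of identifiers.

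The design written before the data were examined assumed peak lists or values per library, with tests between immunoprecipitates. The tables held FPKM without replicates, so the part of that design for normalised values without replicates was used. For each gene in both tables the log2 ratio was log2((second + 1)/(first + 1)), with a pseudocount of 1 FPKM, which understates the difference for low genes. A gene in 1 table only was given no ratio. The named genes were the 10 highest and 10 lowest ratios among genes above the median mean level of 4.93 FPKM, DNMT1, NSUN2, and members of the gene lists. With no test to pass, list members were named when they differed by at least 2-fold on this scale, up to the 4 largest differences per list. That reading of the rule was made after the tables had been seen. Other list members were added as examples after their values were seen.

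The 17 gene lists were fixed before the data were examined. Each list with at least 5 genes in both tables had its median log2 ratio placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 classes. A list outside the middle 95% is described as such. One of the lists inside it is not reported here. The percentile describes these tables and is not a test. Among 15 lists about 5% would fall outside by chance if genes varied independently. Tested on simulated data with 14270 genes, 11 of 200 lists of 40 genes with no shift fell outside, and 193 of 200 lists shifted by 0.3 fell above it. The simulated ratios were independent between genes, so the first of these rates was set by the design. Genes of the real lists can share a locus or be close paralogs, and most lists are smaller. Neither rate need hold for them.

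Absolute depth is unknown. Relative depth was estimated from genes under 1 FPKM in both tables, where 1 fragment sets the step between values, as the most common ratio at which equal small numbers of fragments lie. The estimate was 2.13 with a bootstrap SD of 0.01 over 200 resamples, which covers the choice of genes only and not the choice of peak. The peak read as 1 fragment to 1, at a log2 ratio of -1.09, held 160 genes, and the peak at -0.09, read as 2 fragments in the second table to 1 in the first, held 142. Were the latter 1 to 1, the depths would be nearly equal, and peaks of similar size would lie at -1.09 and 0.91, where 160 and 73 genes were found. The range searched was set after the distribution of ratios had been seen, and it left out the peak at -0.09. The rule for choosing between peaks was changed after it missed a simulated ratio. In the final form the 4 simulated ratios were recovered within 0.48%. All 4 lay inside the range searched, so their recovery does not bear on the choice between the peaks at -1.09 and -0.09. A deeper table lists more genes of low level, so being listed in 1 table only is not read as a difference in expression.

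Gene density was the number of listed genes starting within 1 Mb of a gene's start, and was examined after the data had been seen. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The alternatives tried were a pseudocount of 0.1, no filter on level and several settings added after the data had been seen. Genome sequence was not used here, so GC content was not analysed here. Peaks were not analysed here.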

Results

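U2OS is an established human osteosarcoma cell line. The labels described 6 RNA samples from it: 1 input from control cells (shNC), 1 input from cells with DNMT1 knocked down by a short hairpin RNA (shDNMT1), and 2 samples of each kind of cell in which RNA was co-immunoprecipitated with a mutant of NSun2, an enzyme that methylates cytosine in RNA. DNMT1 is the enzyme that maintains cytosine methylation in DNA. The series title links DNMT1 and NSun2 expression to cytosine methylation in DNA and in mRNA and to apoptosis of osteosarcoma cells. The values analysed here came from 2 deposited tables of FPKM per gene, in which fragments are scaled by transcript length and by the total of mapped fragments. Neither table named a sample, a condition, or input against immunoprecipitate, so they are called the first and the second table, and neither stands for control or knockdown cells. The comparison of shDNMT1 with shNC cells and that of immunoprecipitate with input were therefore not made. Each gene had 1 value per table, with no replicate, no SD and no test, and the differences given are between these tables only.

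The first table listed 15167 genes and the second 16824, and 14270 genes were in both. At 1 FPKM or more the numbers were 11427 and 11421. The genes in the second table only numbered 2554, with a median of 0.19 FPKM, and those in the first table only numbered 897, with a median of 0.35 FPKM. The absolute depth of either table is unknown. From the values of low genes, the second table rested on an estimated 2.13 times as many fragments as the first, an estimate that depends on which of several peaks of the ratios is read as 1 fragment to 1. Across the genes in both tables, which are not independent replicates, log2 FPKM had a Pearson correlation of 0.942 and a Spearman correlation of 0.961.

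DNMT1, the target of the knockdown, was listed at 23.3 FPKM in the first table and 9.36 FPKM in the second, a log2 ratio of second over first of -1.23 on the log2(FPKM + 1) scale. Its locus (chromosome 19, 10133345 to 10231286, hg38; ENSG00000130816) also held S1PR2, listed at 3.71 and 2.54 FPKM. NSUN2 (chromosome 5, 6599239 to 6633291; ENSG00000037474), the gene of the precipitated protein, was listed at 559 and 1147 FPKM, a log2 ratio of 1.04, and ranked 112 and 38 among all genes. The labels state that the cells were transfected with an NSun2 mutant plasmid, and the FPKM of NSUN2 does not separate plasmid RNA from RNA of the chromosomal gene.

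Among the enzymes that write or remove 5-methylcytosine in RNA and the proteins that bind it, 13 of the 15 genes in both tables were higher in the second. The median log2 ratio was 0.32, at percentile 98.0 of random gene lists matched on expression. On the log2(FPKM + 1) scale, NSUN2 was the member with a difference of at least 2-fold. With the ratios centred on the median of all genes in both tables, its log2 ratio became 0.98, just under 2-fold. YBX1, an RNA-binding protein that recognises the modification, was listed at 80.2 and 129 FPKM. ALYREF, an mRNA export factor that binds it, was listed at 65.7 and 77.7 FPKM. NSUN5, a methyltransferase of ribosomal RNA, was one of the 2 that were lower in the second table, with 46.9 and 38.1 FPKM. TRDMT1, a methyltransferase of transfer RNA also called DNMT2, was near the floor at 0.053 FPKM in the first table and at 0.99 FPKM in the second. NSUN3, at 1.38 and 3.50 FPKM, and TRDMT1 each had a log2 ratio of 0.92 on the log2(FPKM + 1) scale. Without the pseudocount their folds were 2.53 and 18.6.

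The DNA methylation machinery held 17 genes in both tables, of which 13 were higher and 4 lower in the second. Its median log2 ratio of 0.20 lay at percentile 75.2, inside the middle 95% of random lists. Besides DNMT1, TDG differed by at least 2-fold on the log2(FPKM + 1) scale. DNMT3A, at 1.30 and 0.49 FPKM, had a log2 ratio of -0.63 on that scale. TDG, a DNA glycosylase of the active demethylation pathway, was listed at 2.42 and 6.18 FPKM. UHRF1, which recruits DNMT1 to newly replicated DNA, was listed at 45.4 and 49.8 FPKM, and the de novo methyltransferase DNMT3B at 7.13 and 8.36 FPKM.

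**Figure D1:**
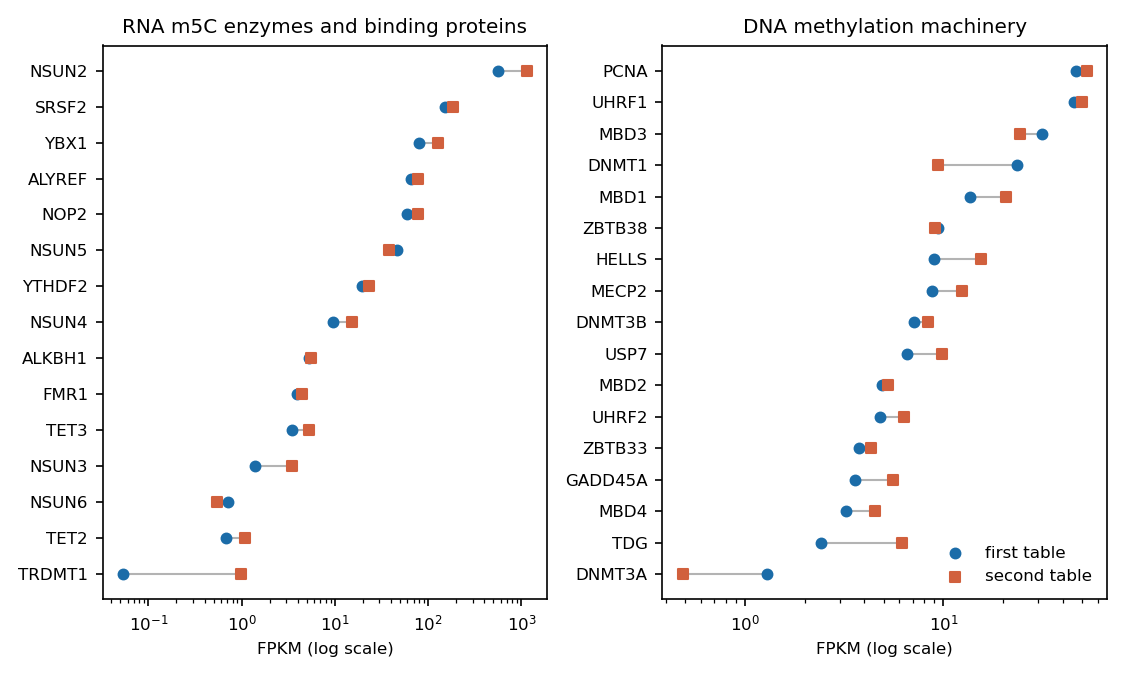
FPKM (log axis) of the genes listed in both tables for RNA m5C enzymes and binding proteins (left, 15 genes) and DNA methylation machinery (right, 17 genes). Circles are the first table and squares the second, with 1 value per gene and table and no error. NSUN2 sits at 559 and 1147 FPKM and DNMT1 at 23.3 and 9.36 FPKM.

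Of the 7135 genes above the median level of 4.93 FPKM, 97.4% lay within 2-fold between the tables on the log2(FPKM + 1) scale. On that scale 121 were at least 2-fold higher in the second and 62 at least 2-fold lower. The median log2 ratio of the 7135 genes was itself 0.08. With the ratios centred on 0.05, the median of all 14270 genes in both tables, the counts became 88 and 79. The excess of higher genes thus depended on the scaling between the tables, and centring does not show its source. The counts also depended on the level filter, with 58 and 31 at a mean of at least 10 FPKM and 291 and 240 with no filter. Among genes sharing no locus with another gene they were 69 and 24. The gene that stood highest in the second table was NDUFC2-KCTD14, a readthrough transcript at 1.07 and 11.97 FPKM. It shared its locus with NDUFC2, which was listed at 74.9 and 82.4 FPKM. LSM1, part of a complex that promotes mRNA decapping, was listed at 3.36 and 13.7 FPKM, and CNOT7, a deadenylase of the CCR4-NOT complex, at 9.78 and 27.7 FPKM. LSM1 shared its locus with ASH2L and BAG4, and CNOT7 with VPS37A. F3, the tissue factor that starts coagulation, had 3.13 and 12.4 FPKM, and SERPINE2, an inhibitor of thrombin, 6.64 and 19.6 FPKM. SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, had 2.08 and 8.03 FPKM. The other genes of the 10 highest were PYURF, which shared its locus with HERC3 and NAP1L5, NAA20, LINC01184 and TXNDC15.

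The gene that stood lowest in the second table was 7SK, at 137.8 and 5.66 FPKM. It shared its locus (chromosome 6, 52995620 to 52995950) with RN7SK, a second identifier listed at 43878 and 30346 FPKM, so how fragments were divided between them enters its ratio. STK11, a tumour suppressor kinase that activates AMPK, was listed at 24.8 and 1.33 FPKM, a log2 ratio of -3.47. PIK3CA, a catalytic subunit of phosphatidylinositol 3-kinase, was listed at 16.4 and 1.68 FPKM, a log2 ratio of -2.69. Both shared their locus with a second gene, CBARP for STK11 and KCNMB3 for PIK3CA, and neither partner exceeded 4.12 FPKM. One of the 2 identifiers of SCARNA2, a guide RNA of Cajal bodies, was listed at 133 and 16.5 FPKM, while the sum of both was 554 and 319 FPKM. CGA, the alpha subunit of glycoprotein hormones, had 15.1 and 2.31 FPKM, and IDH2, a mitochondrial isocitrate dehydrogenase, 20.2 and 5.41 FPKM. RAB26, CDK18, AGFG2 and the alkaline phosphatase ALPI completed the 10 lowest.

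Abundant noncoding RNAs were lower in the second table in 11 of 13 identifiers, with a median log2 ratio of -0.35 at percentile 0.55. Some of these RNAs have 2 identifiers, and with the identifiers of each gene name summed 9 of 11 were lower, the median was -0.19, and it lay inside the middle 95% of random lists at percentile 9.45. RN7SK, which holds the elongation factor P-TEFb inactive, had a log2 ratio of -0.53. RMRP, the RNA of RNase MRP, summed to 26183 and 18387 FPKM over its 2 identifiers. RN7SL1, an RNA of the signal recognition particle, had a log2 ratio of -0.46 for the identifier in both tables, but a second identifier was listed in the second table only and brought the sums to 70077 and 68231 FPKM, a log2 ratio of -0.04. RN7SL1, RN7SL2, RN7SK, RMRP and RPPH1 together made up 34.7% of the summed FPKM of the first table and 32.0% of the second, which is a share of FPKM and not of fragments.

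Histone genes were lower in the second table in 67 of 80, with a median log2 ratio of -0.52, below that of every one of 10000 random lists. Of the 13 that were higher, the abundant ones were H2AFV, H2AFY, H3F3A, H2AFZ and H3F3B. The others, all with a HIST name, were listed at no more than 5.56 FPKM in either table. H3F3A was listed at 79.2 and 120.8 FPKM, H2AFZ at 113.9 and 151.6 FPKM and H3F3B at 110.5 and 134.6 FPKM. HIST1H4C was listed at 1105 and 770 FPKM and HIST1H3C at 1677 and 1110 FPKM. HIST2H2AA3 and HIST2H2AA4, at 2128 and 1601 FPKM and at 1821 and 1363 FPKM, are nearly identical copies whose fragments the upstream counting could divide. On the log2(FPKM + 1) scale, H2BFS, HIST1H4B and HIST2H2AB were at least 2-fold lower in the second table. Of the 2 that were at least 2-fold higher on that scale, HIST3H3 was listed at 0.47 and 2.08 FPKM. Mitochondrially encoded genes were lower in 12 of 15, with a median of -0.27 at percentile 2.44. MT-CO1 was listed at 7457 and 5903 FPKM and MT-CYB at 1377 and 837 FPKM, while MT-RNR1, a ribosomal RNA, was listed at 272 and 434 FPKM. Among the 10 mitochondrial genes sharing no locus the median, -0.31, lay inside the middle 95% of random lists.

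Cancer-testis genes, which are normally restricted to germ cells, were higher in the second table in 8 of 9, with a median log2 ratio of 0.33 at percentile 98.4. MAGEA3 was listed at 36.7 and 44.4 FPKM, MAGEA6 at 45.9 and 59.6 FPKM and PAGE1 at 18.4 and 23.2 FPKM. MAGEA3 and MAGEA6 are close paralogs, as are the GAGE genes of the list. Cytoskeletal genes were higher in 19 of 26, with a median of 0.18 at percentile 98.95. Vimentin (VIM) was listed at 262 and 407 FPKM and the tropomyosin TPM4 at 76.5 and 112 FPKM, against 742 and 684 FPKM for filamin A (FLNA). Neither list stayed outside the middle 95% among genes sharing no locus, where the cancer-testis median was 0.32 over 7 genes and the cytoskeletal median 0.03 over 8 genes. The cancer-testis list also came inside with a pseudocount of 0.1, at a median of 0.35.

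Apoptosis genes were higher in the second table in 26 of 41 and lower in 15, with a median log2 ratio of 0.12 at percentile 73.0. PMAIP1 is a pro-apoptotic BH3-only protein also known as NOXA. It was the member with a difference of at least 2-fold on the log2(FPKM + 1) scale, at 4.81 and 11.9 FPKM. BAX was listed at 36.3 and 40.8 FPKM and the kinase AATK at 8.73 and 4.57 FPKM. Autophagy and mTOR genes were higher in 17 of 32 (median 0.02, percentile 26.5), with RPTOR at 18.2 and 19.0 FPKM. Growth factor and MAPK genes were evenly divided, 11 and 11 (median 0.04, percentile 41.8). In that list PIK3CA, the ERK kinase MAPK3 (38.5 and 18.0 FPKM) and the receptor PDGFRB (4.07 and 1.08 FPKM) were at least 2-fold lower in the second table, and the adaptor GRB2 was listed at 39.7 and 44.0 FPKM.

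Cell cycle genes were higher in 18 of 25 (median 0.20, percentile 95.3), with the phosphatase CDC25C at 4.20 and 9.58 FPKM and cyclin B1 (CCNB1) at 66.0 and 109 FPKM. Interferon response genes were higher in 12 of 16 (median 0.31, percentile 94.2), with IFI44 at 1.88 and 5.78 FPKM and ISG15 at 198 and 158 FPKM. The ribosomal proteins divided into 42 higher and 41 lower (median 0.01, percentile 86.4), and the glycolysis genes into 7 higher and 11 lower (median -0.04, percentile 36.5). These lists, too, lay inside the middle 95%. The cell cycle list went outside it among genes sharing no locus (median 0.37), and the interferon list with a pseudocount of 0.1 (median 0.53). Centring the ratios turned the sign of the ribosomal, autophagy and growth factor medians. Of the 15 lists with at least 5 genes in both tables, 6 lay outside it, counting the noncoding RNAs by identifier.

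**Figure D2:**
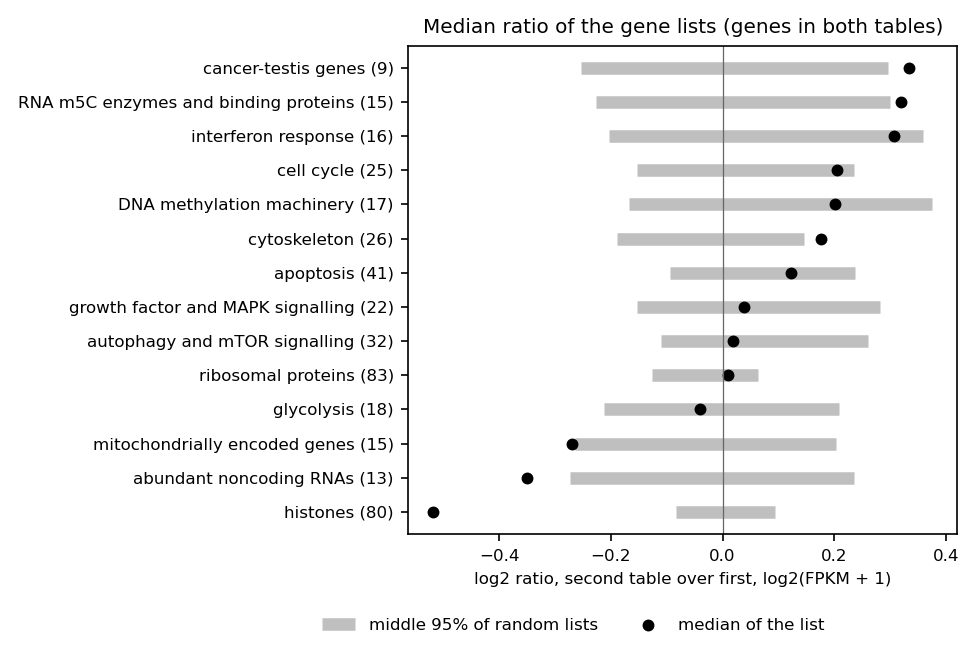
Median log2 ratio of second over first table (horizontal axis, log2(FPKM + 1)) for each gene list reported that had at least 5 genes in both tables. The number of genes in both tables is given in brackets. Points are list medians and grey bars the middle 95% of 10000 random lists matched on expression. Histones lie farthest to the left at -0.52 and cancer-testis genes farthest to the right at 0.33.

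Of 14 osteoblast and bone matrix genes, 3 were listed in the first table and 7 in the second. The alkaline phosphatase ALPL was listed at 78.4 and 38.1 FPKM and the collagen COL1A1 at 3.04 and 0.45 FPKM, both at least 2-fold lower in the second table. RUNX2, a transcription factor of osteoblasts, was listed in the second table only, at 0.81 FPKM. Of 13 markers of other cell types, 4 and 5 were listed, EPCAM at 2.20 and 0.55 FPKM and the others at no more than 2.18 FPKM. Both lists had fewer than 5 genes in both tables and were given no percentile.

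The ratio between the tables also varied along the chromosomes. Among the 7135 genes above the median level, split into 5 classes of equal size by the number of listed genes within 1 Mb, the class with the fewest had a median log2 ratio of 0.32 and the class with the most had -0.14. Across these genes, which are not independent replicates, the Spearman correlation of the ratio with gene density was -0.38. The 6 lists outside the middle 95% of random lists also lay outside when the random lists were matched on gene density too. The RNA m5C list did so narrowly, at percentile 97.75. For the mitochondrial list this match is no control. All its genes lie within 1 Mb of each other, so it was matched to nuclear genes of low density, whose ratios ran higher.

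**Figure D3:**
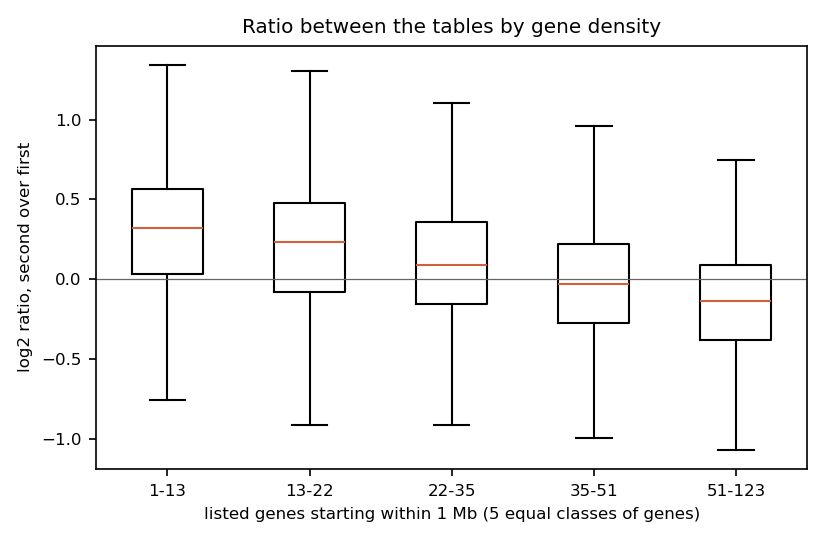
Log2 ratio of second over first table (vertical axis) for 7135 genes in 5 equal classes by the number of listed genes starting within 1 Mb (horizontal axis). Lines are medians, boxes the middle 50% of genes and whiskers reach to at most 1.5 times the box height, with genes beyond them not drawn. The median falls from 0.32 in the least dense class to -0.14 in the densest.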

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

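No paired analysis was possible because the tables name no replicate. The alternatives planned for peak lists, for counts, for the immunoprecipitates (replicate block, leave-one-out) and for peak sequence were not run, since the values needed were not among those analysed. A pseudocount of 0.1 and no level filter were planned, and the other settings were chosen after seeing the data. Of all results recomputed under these settings, 204 kept their side of the middle 95% or moved little, and 10 values moved further. Many of the 204 could hardly change, so their number does not measure robustness. Filters on level or locus leave the ratio of a single gene as it was. Centring and equal protein-coding totals move all genes by nearly the same amount, which leaves list percentiles almost as they were. In 5 cases a list median came inside the middle 95% of random lists and in 2 cases it went outside, and no called value changed sign. The counts of genes at least 2-fold higher and lower in the second table, 121 and 62, became 291 and 240 with no filter on level, 58 and 31 at a mean of at least 10 FPKM, and 69 and 24 for genes sharing no locus; with a pseudocount of 0.1 they became 179 and 97. Fewer or more genes entered under the filters by construction. A smaller pseudocount makes every ratio larger in size, so the counts could only rise with it, also by construction. With a pseudocount of 0.1 the cancer-testis median became 0.35 and came inside, and the interferon median became 0.53 and went outside. Among genes sharing no locus, where the lists are smaller, the cancer-testis (0.32), mitochondrial (-0.31) and cytoskeletal (0.025) medians came inside and the cell cycle median (0.37) went outside. With the identifiers of one gene name summed, the noncoding median became -0.19 and came inside; the sum adds the RN7SL1 identifier listed in the second table only, which takes the ratio of RN7SL1 from -0.46 to -0.04. The cause of the other list changes was not tested. The histone and RNA m5C lists stayed outside under the settings run for them. The RNA m5C list did so narrowly with random lists matched on gene density too. Its median there was 0.319 against an upper limit of 0.316. None of the settings left out its member NSUN2, whose FPKM does not separate plasmid RNA from RNA of the chromosomal gene. Centring the ratios on the median of all genes in both tables shifted them by -0.05, and equal protein-coding totals shifted them by 0.0009. Neither moved a 2-fold count beyond 1.5 times, but centring brought the higher and lower counts to 88 and 79. Centring also turned the sign of 3 uncalled list medians near 0, ribosomal (-0.04), autophagy (-0.03) and growth factor (-0.02), and genes sharing no locus turned that of growth factor (-0.0008) and glycolysis (0.18). With a pseudocount of 0.1 the log2 ratios of NDUFC2-KCTD14, STK11 and PIK3CA became 3.37, -4.13 and -3.21. Absolute depth is unknown and relative depth was only estimated, so no counting error can be given for low genes.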

Other observations

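The tests of gene density within chromosomes, of the NSUN2 level and of epithelial genes were chosen after the results they bear on had been seen. The limits for the depth test and for TERT were set before those values were seen. No biological explanation was tested for any of these patterns, since the tables belong to no group of the design.

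The epithelial keratins KRT8 and KRT18 were listed at 1597 and 1410 FPKM and at 1293 and 1196 FPKM in the first and second table, and KRT7 at 230 and 319 FPKM. The placental alkaline phosphatase ALPP was listed at 342 and 214 FPKM, and CDKN2A, which encodes the cell cycle inhibitor p16, at 155 and 119 FPKM. These genes, other than the list member CDKN2A, were outside the fixed lists, and all of them were singled out after their values were seen.

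The ratio of the second to the first table was lower in gene-dense regions. A difference in depth is argued against as the whole cause, because the trend held among 1277 genes with a mean of at least 50 FPKM, with a Spearman rho of -0.35. A bias that follows local base composition may contribute: the median rho within chromosomes was -0.27, negative in 22 of 23, so the trend does not rest solely on differences between whole chromosomes, although it was weaker within them than the -0.38 over all genes and the chromosome medians ran from -0.13 on chromosome 19 to 0.26 on chromosome 13 apart from mitochondrial genes. Density only stands in for composition here, and a regulated difference between gene-dense and gene-poor regions would give the same trend, so the test does not separate them. The ratio rose with gene span, with a rho of 0.21. Span and density were not separated here, so this is not evidence against the density trend.

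NSUN2 was far above the genes around it. A gain of the region on chromosome 5 stays open: the highest of the 3 listed genes within 1 Mb reached at most 0.041 of the NSUN2 level, but a gain scales each gene from its own level, so this ratio decides nothing. These neighbours were higher in the second table too, with log2 ratios of 0.71 for MED10, 0.55 for SRD5A1 and 0.08 for PAPD7, against 1.04 for NSUN2. The 296 genes of chromosome 5 above the median level had a median of 0.23. A gain carried by the cells of both tables would not change a ratio between them, so these ratios do not bear on it. RNA from the transfected plasmid cannot be told apart from RNA of the chromosomal gene: NSUN2 stood 9.47 times above the highest other family member in the first table and 14.7 times in the second, and the limit set for both tables was 10. FPKM per gene does not show the mutation that would separate them.

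Epithelial keratins were abundant in tables from a line labelled osteosarcoma. RNA of epithelial-type cells stays open: apart from KRT7, KRT8 and KRT18, which prompted the question, 9 and 7 of the other 18 epithelial genes reached 1 FPKM, against 9 and 8 of 21 mesenchymal genes. The smaller difference in share between the lists was 0.79 percentage points, in the second table, and in both tables the mesenchymal share lay within the 95% Wilson interval of the epithelial one (29.0% to 71.0% and 20.3% to 61.4%), which takes genes as independent. Single members of both lists went both ways. Among epithelial genes, ELF3 was listed at 45.9 and 39.9 FPKM and CLDN4 at 28.0 and 22.9 FPKM. CDH1 was listed at 8.42 and 0.39 FPKM, EPCAM at 2.20 and 0.55 FPKM and KRT19 at 0.20 FPKM in the first table only. Among mesenchymal genes, COL5A1 was listed at 39.0 and 46.0 FPKM and CDH2 at 7.41 and 16.2 FPKM. Near the floor were THY1 at 0.080 and 0.032 FPKM and COL6A3 at 0.13 and 0.060 FPKM. SPARC, at 0.033 FPKM, and COL3A1, at 0.096 FPKM, were listed in the second table only. A line other than the labelled one also stays open, since TERT, described in general as silent in U2OS, was listed at 2.11 and 0.49 FPKM, and the limit set for both tables beforehand was 0.5. CDKN2A is also described in general as silent in U2OS, but its value had been seen, DNMT1 knockdown could bear on it, and it was not used as a test.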
